A study of Mus musculus with 2 samples.

How the data were processed

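The data were 2 single-cell RNA libraries from full-thickness back skin, 1 from a WT mouse and 1 from a Card14KI mouse. Per the labels' protocols, skin was digested with enzymes for 73 min, dispersed mechanically and cleared of dead cells, libraries were made with the 10x Genomics 3' gene expression kit, version 3.1, and sequenced in paired-end mode on a DNBSEQ-G400. The deposited values are UMI counts per gene and barcode, whole numbers that were not normalized, for barcodes that the authors' pipeline called as cells. Per the submitters' processing notes, counting used Cell Ranger 6.0.2 with the mm10 build, whereas per the file headers the counting software was Cell Ranger 5.0.0. Which version made the count tables is not known, and the annotation release is not given in the sources used here. The kit counts the 3' end of transcripts, so a count is not a full-length measure, and reads of near-identical genes such as the Lce1, Sprr2, Serpinb3, stefin and hair keratin-associated families can be lost or split. The tables held 31053 features, of which 31011 were located by Ensembl gene ID in the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names; coordinates are 1-based.

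Barcodes with under 500 detected genes (609 in WT and 393 in Card14KI) or with 20% or more mitochondrial UMIs (164 and 132) were removed, 681 and 435 in all. Scrublet scores were computed per library. Its automatic threshold marked 7 and 8 cells (0.161% and 0.275%), which was taken as not having worked, so the cells with the highest scores were removed up to the rate expected of the platform, 0.8% per 1000 barcodes, or 174 (4.01%) and 78 (2.68%) cells. This left 4161 WT and 2835 Card14KI cells with 51040861 and 38365728 UMIs, a median of 2425 and 2211 genes per cell, and a median mitochondrial share of 2.84% and 2.11%. A count of 0 allows a share of up to 0.0721% of kept WT cells and 0.106% of kept Card14KI cells, taking 3 counts as the floor.

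Both libraries were clustered together on log counts scaled to 10000 UMIs per cell, with 2000 variable genes ranked within each library, 30 principal components, 20 neighbours and Leiden resolution 1. Genes of the response lists and cell cycle, mitochondrial, ribosomal and haemoglobin genes were left out of the variable genes, so that these genes did not form the clusters. Markers for 30 classes (14 broad) were fixed before the data were examined. A cluster took the class whose markers led it, with 3 or more markers detected in 10% of its cells. Many markers of keratinocyte and fibroblast classes are also members of the hemidesmosome, cornified envelope, hyperproliferative or matrix lists, so the naming did use genes that were compared. All 27 clusters were named. Scoring by fold over the mean of the other clusters left fibroblast clusters without a name, so fold over the median was used instead, a choice made after the clusters were seen. The pigment cell cluster also held Schwann cell genes. The authors' own cell annotation was not used here, and names rebuilt in this way can differ from those of the study.

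With 1 mouse per group no test, p-value or standard error was computed, and cells were not treated as replicates. UMIs were summed over the cells of a class in each library and scaled to the total UMIs of the class, as CPM. Sums have exact Poisson intervals, ratios of CPM exact conditional binomial intervals and shares exact Clopper-Pearson intervals, at 95%; differences of shares have Newcombe intervals, built from the Wilson interval of each share. All cover counting error only, since 1 library per group holds no spread between animals. Log2 ratios are of CPM + 10, which lessens the ratio of low genes, and folds are plain ratios of CPM. A fold against 0 counts was computed against 3 counts and is a lower bound. Shares of cells with a UMI were also computed with each cell thinned to 2000 UMIs and shallower cells left out, and fibroblasts served as the background class for immune and keratinocyte cytokine genes.

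The 19 gene lists were also fixed before the data were examined. They covered IL-17 and IL-23 ligands and receptors, genes that IL-17 raises in keratinocytes, IL-36 genes, the other IL-1 family, CARD14, BCL10, MALT1 and NF-kB genes, and hyperproliferative, cornified envelope, and basal and hemidesmosome genes. The rest were cell cycle, chemokines, interferon response, type 2 inflammation, MHC class I, MHC class II, extracellular matrix, T cell effector, growth factor and STAT3, immediate early and heat shock, and sex-linked genes. A list was summarised by the median log2 ratio over members with 10 or more UMIs, its interval over 1000 Poisson draws, and its percentile among 10000 random lists of the same size matched on mean CPM in 20 bins, which describes these libraries and is not a p-value. Neutrophils and lymphatic endothelial cells, with 30 or more cells in each library, entered for the lists only. Lists in B or plasma cells are not reported.

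Genes were named by a rule fixed before the data were examined: the 12 highest and 12 lowest by log2 ratio in keratinocytes and the 6 highest and 6 lowest in other classes with 100 or more cells in each library. Eligible genes had 20 or more UMIs and a UMI in 5% of cells in the library with the higher CPM, and there at least 25% of the CPM of the top class. In keratinocytes members of the IL-17, IL-36 and CARD14 lists were named as well, and of any other list up to 4 members in a class, the 2 with the largest ratio each way. Cytokine genes of the positive-cell table were named in every class. Not every gene that met the rule is reported here. Ranking 6 and 6 genes in basal and suprabasal keratinocytes apart, adding Il1f6 to the positive-cell table, the look at named genes per cluster and the collagen sum were chosen after values were seen.

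The measures of levels, lists and shares were tested on simulated WT and Card14KI libraries, drawn at the mean depth of each real library from the profile of real WT cells. Counts were Poisson draws from 1 profile, so simulated cells differed in depth only and the intervals were bound to hold near their set level. UMIs that lie in a few cells were not simulated. Cell filtering, doublet removal, clustering and naming were not tested. Of 50 genes each with folds of 0.25, 0.5, 2 and 4, the median estimated folds were 0.245, 0.485, 1.95 and 3.98, and 96%, 98%, 98% and 96% of the intervals held the true fold. True folds were taken relative to the library total after the changes, which moves unchanged genes slightly off 1. Among 7227 genes with no simulated difference the median estimated fold was 0.980, and 95.7% of the intervals held the true fold. A raised list of 20 genes had a median of 0.82 at percentile 100, and an unraised list of 20 genes a median of -0.03 at percentile 38.1. In 1 simulated profile, drawn at a shallow and a deep sequencing depth, the share of cells with a UMI was 62.3% and 95.3% as counted and 46.3% and 45% after thinning.

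Alternatives fixed in advance were other cell filters (none, or 1000 genes and under 10% mitochondrial UMIs), no doublets removed, Scrublet's automatic threshold, each library clustered alone, resolutions of 0.5 and 2, response genes kept for clustering, a median-of-ratios scaling over genes with 20 or more UMIs, CPM without mitochondrial, ribosomal and haemoglobin genes, the mean of each cell's CPM, a pseudocount of 1 CPM, the same cluster weights in both libraries for keratinocyte genes and for the lists (clusters with 30 or more cells in each), list members with 1 or 50 UMIs, and thinning to 1000 UMIs. Added after the data were seen were naming by the mean of the other clusters, leaving out hair clusters, the same cluster weights for single genes of other classes, and leaving out the cell of each library with the most UMIs of a gene. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, with random seed 1.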

Results

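Whole back skin was profiled by droplet single-cell RNA sequencing in 1 wild-type (WT) and 1 Card14 knock-in (Card14KI) mouse on the C57BL/6 background, both 12 months old. CARD14 is a scaffold protein that links receptors of skin cells to the NF-kB pathway through BCL10 and MALT1. The knock-in animals are a model of pityriasis rubra pilaris, a scaling and inflammatory skin disease, and the series title concerns the IL-17 axis and IL-36 signalling. The deposited tables held 5016 barcodes and 54816411 UMIs (unique transcript molecules) in the WT library, and 3348 barcodes and 41460580 UMIs in the Card14KI library. After filtering, 4161 WT and 2835 Card14KI cells were kept, with a median of 7344 and 6875 UMIs per cell. With 1 mouse per group no difference here has a replicate check. Every value describes these libraries, and intervals are 95% intervals that cover counting error only. They are exact for levels, ratios and shares, and Newcombe intervals for differences of shares. For list medians and for the neutrophil and hair transcript percentages they come from Poisson draws. UMIs that lie in a few cells vary more than a Poisson interval says.

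The first comparison asked which cell types the libraries held. Keratinocytes were 23.4% of kept WT cells and 29.9% of kept Card14KI cells, a difference of 6.59 percentage points (4.47 to 8.71), which was 2.80 points with no cell filter. Within them, the clusters named suprabasal keratinocyte were 313 cells (7.52%) in WT and 481 (17.0%) in Card14KI, and those named basal keratinocyte 266 (6.39%) and 358 (12.6%). The suprabasal class includes a Krt17 and Krt79 cluster of 154 WT and 200 Card14KI cells, which took the name hair follicle keratinocyte when clusters were named by the mean of the others. The basal class includes a cluster that shares top genes with sebocytes and a cluster led by basal and suprabasal markers alike. The basal class held 353 WT and 174 Card14KI cells with no cell filter, and 224 and 179 at resolution 0.5, so its order turned under both. Hair follicle keratinocytes were 247 WT and 9 Card14KI cells, or 401 and 209 when named by the mean, and no cluster took that name with either other cell filter. Cells of the cluster named hair shaft or matrix were 146 and 1 under both ways of naming, although the genes that lead it, such as Krt71, Krt25 and Tchh, are those of the inner root sheath. Clusters this uneven may mark a library and not a cell type. Immune cells were 17.8% (16.7 to 19.01) of the WT library and 11.6% (10.5 to 12.9) of the Card14KI library.

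Lymphocytes were 375 cells (9.01%) in WT and 147 (5.19%) in Card14KI, lower by a difference of -3.83 points (-5.01 to -2.62). Mononuclear phagocytes, the monocytes, macrophages and dendritic cells, were 241 (5.79%) and 111 (3.92%), a difference of -1.88 points (-2.87 to -0.85). Neutrophils were 45 (1.08%) and 33 (1.16%), and the difference of 0.08 points (-0.41 to 0.62) was not detectable at this depth. Within immune cells alone, lymphocytes were 50.6% (46.9 to 54.3) in WT and 44.5% (39.1 to 50.1) in Card14KI. Mononuclear phagocytes were 32.5% and 33.6% of immune cells, B or plasma cells 10.8% and 11.8%, and neutrophils 6.07% (4.46 to 8.04) and 10% (6.98 to 13.8). Sebocytes were 162 (3.89%) and 163 (5.75%), fibroblasts 2161 (51.9%) and 1385 (48.9%), and lymphatic endothelial cells 102 (2.45%) and 76 (2.68%). B or plasma cells were 80 (1.92%) and 39 (1.38%), and the cluster named melanocyte 23 and 32 cells, a name that no cluster took with either other cell filter or with response genes kept in. Enzymatic digestion and dead cell removal set which cells enter a library, so these shares are not shares of the tissue. The fibroblast share was 5.30 points higher in Card14KI, in place of a difference of -3.08 points, when clusters were named by fold over the mean of the other clusters, an alternative chosen after the data were seen.

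**Figure D1:**
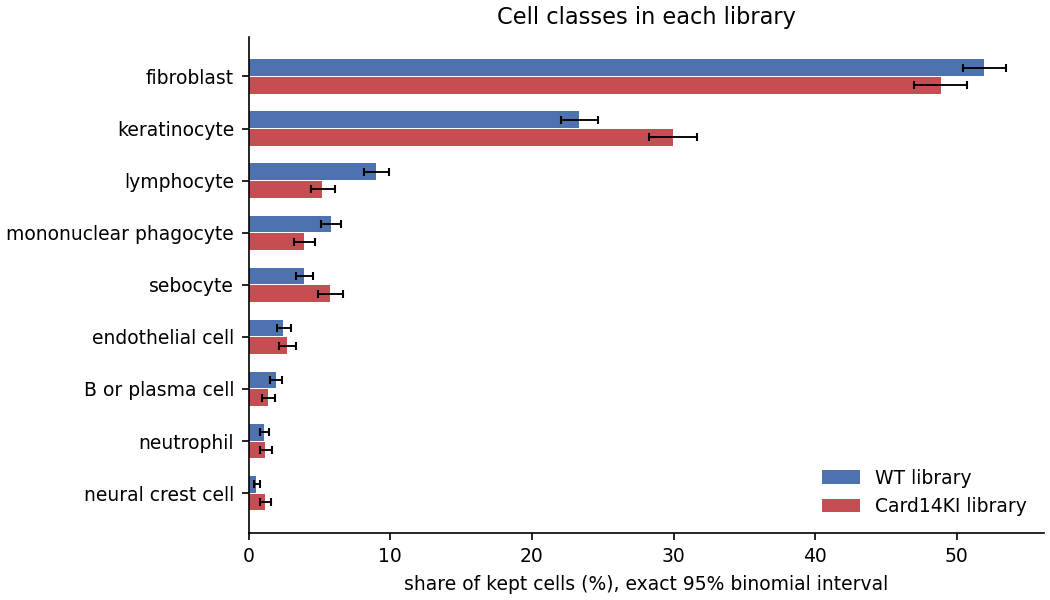
Share of kept cells in each broad class (percent, linear axis from 0), as bars for the WT and Card14KI libraries with exact 95% binomial intervals. Keratinocytes were 23.4% of WT and 29.9% of Card14KI cells, and lymphocytes 9.01% and 5.19%.

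Card14 (ENSMUSG00000013483, chromosome 11, 119307768 to 119345375, plus strand, mm10) was carried mainly by suprabasal keratinocytes. Its level there was 41.5 CPM (counts scaled to the total of the class; 37.2 to 46.2) in WT and 41.7 (38.1 to 45.6) in Card14KI, a ratio of 1.0 (0.872 to 1.16). A Card14 UMI was found in 39.9% of WT and 44.1% of Card14KI suprabasal cells. In basal keratinocytes the level was 4.09 CPM (2.56 to 6.19) and 4.83 CPM (3.58 to 6.36). Fibroblasts, which should lack the gene, held 1.12 and 1.71 CPM, with a UMI in 0.694% and 1.01% of cells, and no lymphocyte had a Card14 UMI. The knock-in changes the protein, so the level checks neither label. Over all keratinocytes Card14 was at 16.3 CPM in WT and 24.1 CPM in Card14KI. However, 393 of the 972 WT keratinocytes lay in the clusters named hair follicle and hair shaft or matrix, which do not enter the suprabasal and basal values. The Krt17 and Krt79 cluster, which took a hair follicle name by the mean of the others, does enter the suprabasal values.

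The main comparison asked how keratinocytes differed. Suprabasal keratinocytes of the Card14KI library carried far more S100a8 and S100a9, the subunits of the antimicrobial alarmin calprotectin, than those of the WT library. S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035, plus strand) was at 1.84 CPM in WT and 155 CPM in Card14KI, a ratio of 84.6 (51.1 to 151). S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721, minus strand) was at 16.3 and 250 CPM, a ratio of 15.3 (12.9 to 18.4). The IL-36 cytokine gene Il1f6, which codes for IL-36 alpha (ENSMUSG00000026984, chromosome 2, 24215418 to 24225702, plus strand), was at 153 and 303 CPM, a ratio of 1.98 (1.86 to 2.12). Lcn2, an iron-trapping antimicrobial protein, was at 7.84 and 25.4 CPM, a ratio of 3.25 (2.47 to 4.32).

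Genes that IL-17 raises in keratinocytes were higher in Card14KI suprabasal cells as a list. Of 13 measured members 9 were higher and 4 lower, with a median log2 ratio of 0.60 (0.42 to 0.66), at percentile 100 of 10000 random lists of the same size matched on mean CPM, and it was 0.25 with all members of 1 UMI or more. The defensin gene Defb14 was at 43.6 CPM in WT and 71.5 in Card14KI. Csf2, which codes for the growth factor GM-CSF, was at 6.98 and 17.2 CPM, but 45 of its 57 WT UMIs lay in 1 cell. The protease inhibitor gene Slpi was at 53.91 and 97.54 CPM, with 317 of 440 WT UMIs in 1 cell, and its log2 ratio went from 0.75 to 1.85 without the top cell of each library, an alternative chosen after the data were seen. Ccl20, which codes for a chemokine that draws CCR6-bearing cells, went the other way in this layer, at 273 and 237 CPM, a ratio of 0.870 (0.823 to 0.921). That direction depended on the cell filter and the naming that followed, since its log2 ratio of -0.19 became 0.03 with no filter and 0.12 with a stricter one. Under both no cluster was named hair follicle keratinocyte, and the suprabasal class held 746 WT and 809 Card14KI cells with no filter and 235 and 373 with the stricter one. Cxcl1, a neutrophil chemokine gene, was at 12.7 and 11 CPM, a ratio of 0.863 (0.660 to 1.13) that did not part from 1.

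IL-36 genes were higher as a list too, with 6 of 7 members higher and a median of 0.26 (0.15 to 0.34), at percentile 98.8. Il1f9, which codes for IL-36 gamma, was at 81.5 CPM in WT and 102 in Card14KI, a ratio of 1.26 (1.14 to 1.38). Il1f5, which codes for the IL-36 receptor antagonist, was at 350 and 448 CPM, a ratio of 1.28 (1.22 to 1.34). Il1f8, which codes for IL-36 beta, was 1.5-fold lower (1.34 to 1.68), at 77.3 and 51.7 CPM. The list's median moved to 0.10 with no cell filter and to 0.47 with the same cluster weights in both libraries. In the other IL-1 family genes 10 of 12 members were higher, with a median of 0.18 (percentile 99.9). Il1rn, the IL-1 receptor antagonist gene, was at 132 and 200 CPM, and the alarmin gene Il33 at 3.06 and 7.79 CPM. Il18 was 1.52-fold lower (1.47 to 1.58), at 697 and 457 CPM, and its log2 ratio went from -0.60 to -0.12 with the same cluster weights.

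CARD14, BCL10, MALT1 and NF-kB genes stood near their matched background in suprabasal cells, with 17 of 22 members higher, a median of 0.10 (0.04 to 0.19) and percentile 91.4. Tnfaip3, which codes for A20, a restraint on NF-kB, had a ratio of 1.53 (1.44 to 1.64), and Rel, an NF-kB subunit gene, a ratio of 1.51 (1.40 to 1.63). Malt1, the paracaspase gene, was 1.48-fold lower (1.19 to 1.84), and Nfkbia, the gene of the NF-kB inhibitor, had a ratio of 0.922. The IL-17 and IL-23 ligands and receptors had 6 members higher and 5 lower, with a median of 0.05 (-0.02 to 0.14) at percentile 81.2. Among them Il23a, the IL-23 subunit gene, was at 9.43 and 19.2 CPM, a ratio of 2.04 (1.56 to 2.67), and Il17rc, an IL-17 receptor gene, at 62.2 and 75.2 CPM.

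The cornified layer and growth lists were mixed in suprabasal cells. Hyperproliferative keratinocyte genes had 11 of 17 members higher and a median of 0.30 (percentile 100), which was 0.097 with no cell filter and 0.078 with all members of 1 UMI or more. The protease inhibitor genes Serpinb3a and Stfa1 had ratios of 14.4 (10.2 to 20.8) and 4.54 (3.74 to 5.55), while the wound keratin Krt6a was 1.60-fold lower (1.40 to 1.84) and the cornified envelope precursor Sprr2a3 was 11.4-fold lower (6.40 to 22.2). Serpinb3a, Stfa1, Sprr2a3 and the Lce genes have near-identical paralogs, so their counts are uncertain. Cornified envelope genes had 11 members higher and 11 lower, with a median of -0.13 (-0.20 to -0.08) at percentile 0.04. Krt1, the main suprabasal keratin, had a ratio of 1.43 (1.40 to 1.46) and Hrnr, a filaggrin-like protein gene, 1.36 (1.33 to 1.40), whereas Lce1m and Lce1a1 were 2.61-fold (2.58 to 2.63) and 2.62-fold (2.57 to 2.67) lower. Basal and hemidesmosome genes had 11 of 12 members higher and a median of 0.35 (percentile 100), with the basal keratin Krt15 at 223 and 451 CPM. Cell cycle genes had 17 of 20 members higher and a median of 0.25 (0.18 to 0.34), which was -0.02 when doublets were kept.

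Chemokine genes were lower in Card14KI suprabasal cells, with 15 of 18 members lower and a median of -0.20 (percentile 0), which was -0.05 when doublets were kept. Ccl27a, which draws skin-homing T cells, was 2.22-fold lower (2.13 to 2.32), and Cxcl14 was 2.45-fold lower (2.15 to 2.80). MHC class II genes had all 9 measured members higher and a median of 0.45 (0.30 to 0.56). Cd74, the class II invariant chain gene, was at 54.8 and 147 CPM and H2-Eb1 at 36.9 and 85.2 CPM, and the log2 ratio of Cd74 went from 1.28 to 0.27 with the stricter cell filter and to 0.54 when doublets were kept. Class II genes also lead the clusters named monocyte (192 WT and 75 Card14KI cells), B cell (49 and 18) and Langerhans cell (15 and 9). Extracellular matrix genes had 18 of 21 members lower (median -0.45). MHC class I genes had a median of 0.17 (percentile 95.1), interferon response genes -0.04 (percentile 11.7), type 2 inflammation genes -0.04 (percentile 13.9), and T cell effector genes 0.00 (percentile 43.8). Epidermal growth factor and STAT3 genes had a median of 0.09 (percentile 86.3), with a mean of opposite sign at -0.05, and immediate early and heat shock genes a median of -0.03 (percentile 5.23).

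Ranked by log2 ratio over all genes, the highest in Card14KI suprabasal cells was Alox8, which codes for a lipoxygenase (ENSMUSG00000020891, chromosome 11, 69183932 to 69197843, minus strand). It had 1 UMI in WT and 824 in Card14KI, a ratio of 582 (104 to 23020). Next came Chil1, a chitinase-like protein gene, at 11.5 and 150 CPM (ratio 13.0, 10.6 to 16.2), then Serpinb3a, the fibrillin gene Fbn2 at 1.59 and 36.1 CPM, the ribonuclease gene Rnase2b at 3.68 and 37.8 CPM, and Stfa1. The lowest were AA467197 at 75.6 and 9.61 CPM, and Btc, which codes for the growth factor betacellulin, at 401 and 90.7 CPM, a level 4.42-fold lower (4.12 to 4.74). Egln3, an oxygen-sensing hydroxylase gene, was 3.45-fold lower (3.12 to 3.82) and Lce1a2 3.04-fold lower. Krtap3-2 was 4.79-fold lower, with its largest WT UMI sum in a hair follicle cluster.

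The excess of S100a9 was present in each of the 3 suprabasal clusters. That of Il1f6 was plain in 2 of them and rested on few UMIs in the other. S100a9 was at 13.0 CPM in WT and 96.1 in Card14KI in the Krt17 and Krt79 cluster, at 5.04 and 273 in the Krt77 and Krt10 cluster, and at 38.3 and 538 in the granular Lor and Flg2 cluster. Il1f6 was at 66.3 and 237 CPM in the Krt77 and Krt10 cluster and at 546 and 1181 CPM in the granular one. In the Krt17 and Krt79 cluster it had only 8 and 25 UMIs, a ratio of 2.54 (1.11 to 6.52), and this low level was not compared with the background class. A UMI of Il1f6 was found in 94 of 313 WT (30.03%) and 179 of 481 Card14KI (37.2%) suprabasal cells. With each cell thinned to 2000 UMIs this was 37 of 305 (12.1%) and 92 of 459 (20.04%), a difference of 7.91 points (2.55 to 13.0), leaving out 8 and 22 shallower cells. For Il1f9 the shares were 39.6% and 41.4%, and 11.5% and 12.6% after thinning. In fibroblasts, whose median depths were 7199 and 5590 UMIs against 14189 and 16668 in keratinocytes, 0.278% and 1.01% of cells had an Il1f6 UMI, or 0.0994% and 0.313% after thinning, and 0.231% and 0.144% had an Il1f9 UMI.

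**Figure D2:**
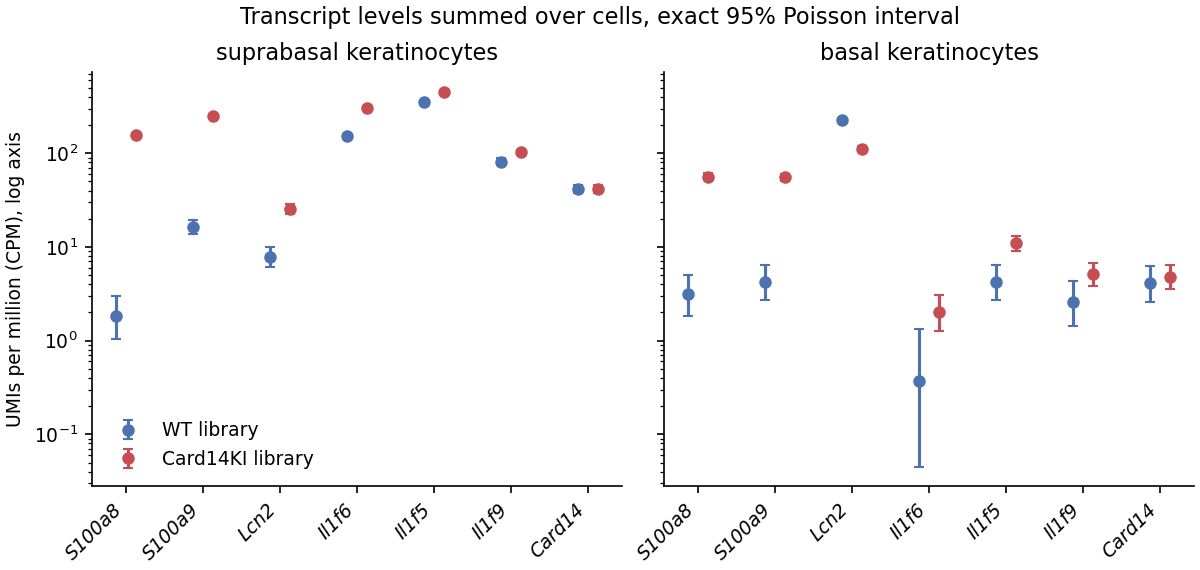
Levels of 7 genes (CPM, log axis) in suprabasal and basal keratinocytes of the WT and Card14KI libraries, as points with exact 95% Poisson intervals. S100a9 in suprabasal cells was at 16.3 CPM in WT and 250 CPM in Card14KI, while Card14 was at 41.5 and 41.7 CPM.

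Basal keratinocytes of the Card14KI library also carried more S100a8 and S100a9, and more transcripts of NF-kB pathway genes. S100a8 was at 3.16 CPM in WT and 56.4 in Card14KI, a ratio of 17.8 (11 to 30.8), and S100a9 at 4.27 and 55.3 CPM, a ratio of 12.9 (8.54 to 20.6). The top cells held 258 of 584 and 165 of 573 of these Card14KI UMIs. Tnfaip3 was at 145 and 282 CPM (ratio 1.95, 1.80 to 2.11), Nfkbia at 814 and 1474 CPM (ratio 1.81, 1.75 to 1.87), Rel at 88.3 and 156 CPM (ratio 1.77, 1.60 to 1.96), and Zc3h12a, an RNA-degrading brake on inflammation, at 31.8 and 66.0 CPM. Most WT basal cells (165 of 266) came from a cluster that shares top genes with sebocytes. Most Card14KI basal cells (229 of 358) came from a cluster led by basal (Krt14, Krt5, Krt15) and suprabasal (Krt1, Krt10, Krtdap) markers alike. At resolution 0.5 the class named basal held 224 WT and 179 Card14KI cells and the suprabasal class 414 and 710. Gene levels were not computed at that resolution, so these basal differences may not be those of the basal layer. With no cell filter no cluster was named hair follicle keratinocyte, and the class named basal held 353 WT and 174 Card14KI cells. The values of that setting therefore compare other sets of cells. Many of them turned direction, and the log2 ratios of S100a8 and S100a9 went from 2.33 and 2.19 to 0.26 and 0.27. With the same cluster weights those of Tnfaip3 and Nfkbia went from 0.92 and 0.85 to 0.38 and 0.37.

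CARD14, BCL10, MALT1 and NF-kB genes had 18 of 22 members higher in Card14KI basal cells, with a median of 0.32 (0.21 to 0.39) at percentile 100, which was 0.12 with the same cluster weights. Genes that IL-17 raises had 8 of 11 higher and a median of 0.62 (0.53 to 0.72), also at percentile 100. That median was 0.17 with the stricter filter, 0.16 when doublets were kept, 0.38 with the same cluster weights, and 0.028 with all members of 1 UMI or more. Ccl20 (ENSMUSG00000026166, chromosome 1, 83116766 to 83119167, plus strand) ranked first, at 6.51 and 104 CPM. However, 792 of its 1078 Card14KI UMIs lay in 1 cell, and without the top cell of each library its log2 ratio went from 2.79 to 1.33. The neutrophil chemokine gene Cxcl2 was at 15.2 and 67.3 CPM, a ratio of 4.41 (3.51 to 5.62). The log2 ratios of Ccl20 and Cxcl2 both turned negative with no cell filter. Lcn2 went against the suprabasal layer and was 2.03-fold lower (1.87 to 2.20), at 227 and 112 CPM, but its log2 ratio turned to 0.38 with the same cluster weights and to 1.09 with no cell filter. IL-36 genes had 5 of 6 members higher and a median of 0.24 (percentile 99.9) that was 0.043 with the same cluster weights, with Il1f5 at 4.27 and 10.9 CPM. With no cell filter the IL-36 median, the CARD14 and NF-kB median and the log2 ratio of Il1f5 all turned negative.

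Other genes ranked highest in Card14KI basal cells included a growth factor and a decoy receptor. Epgn, which codes for the EGF receptor ligand epigen, was at 64.1 and 307 CPM (ratio 4.78, 4.28 to 5.36), and Il22ra2, which codes for a soluble decoy receptor of IL-22, at 5.39 and 47.4 CPM (ratio 8.79, 6.05 to 13.3). Nppb, a natriuretic peptide gene, was at 3.53 and 55.9 CPM, Fbn2 at 3.16 and 46.7 CPM, and Pdzk1ip1 at 57.1 and 211 CPM. Lower in Card14KI were Emb at 372 and 88.2 CPM (4.22-fold, 3.90 to 4.56), Akr1c13 at 33.3 and 1.93 CPM, Fgfbp3 at 130 and 28.6 CPM, Gsta3, a glutathione transferase gene, at 96.5 and 19.6 CPM, and Sprr2a3 at 31.2 and 1.25 CPM. With no cell filter the log2 ratios of Epgn and Nppb turned negative and that of Emb positive. Cornified envelope genes had 15 of 21 members higher (median 0.52) and hyperproliferative genes 9 of 14 (median 0.69, mean 0.23), with medians of 0.13 and 0.15 under the same cluster weights and the hyperproliferative one at -0.013 with all members of 1 UMI or more, although Krt6a was 2.35-fold lower (2.01 to 2.75). MHC class II genes were all higher (9 of 9, median 0.90), with Cd74 at 52.6 and 289 CPM. Cell cycle genes had 18 of 20 members lower and a median of -0.26 (-0.33 to -0.17), which was 0.04 with the same cluster weights. Immediate early and heat shock genes, which dissociation can raise, had 14 of 20 members higher and a median of 0.49. The other basal medians were 0.31 for hemidesmosome genes, 0.21 for the other IL-1 family, 0.17 for growth factor and STAT3 genes, 0.13 for MHC class I, 0.06 for both the IL-17 ligand and T cell lists, 0.04 for interferon response, -0.02 for chemokines and for type 2 genes, and -0.28 for extracellular matrix genes. With no cell filter the cornified envelope, hyperproliferative, hemidesmosome and MHC class II medians and the log2 ratio of Cd74 turned negative. So did the medians of the other IL-1 family, MHC class I and growth factor genes, while that of cell cycle genes turned positive.

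Over all keratinocytes summed, the 3 lists of the study's question were higher in the Card14KI library. Genes that IL-17 raises had 11 of 14 members higher and a median of 0.80 (0.74 to 0.85), IL-36 genes 7 of 7 and 0.57 (0.46 to 0.69), and CARD14 and NF-kB genes 22 of 22 and 0.42 (0.36 to 0.49), at percentiles 100, 99.97 and 100. These sums compare a WT class with 393 cells of the named hair clusters to a Card14KI class with 10. With the same cluster weights in both libraries the medians were 0.51, 0.47 and 0.10, and with the hair clusters left out, an alternative chosen after the data were seen, they were 0.43, 0.14 and 0.23. With all members of 1 UMI or more the IL-17 list's median was 0.11. The 12 genes ranked highest in Card14KI were Chil1, Fbn2, Alox8, Epgn, Serpinb3a, Krt15, Stfa1, Defb6, Il22ra2, Serpinb2, Sprr2d and BC100530, with ratios from 3.10 for BC100530 to 46.7 for Alox8, whose 19 WT UMIs lay mostly (14) in 1 cell. Sprr2d and BC100530 have near-identical paralogs and are uncertain. The defensin gene Defb6 was at 579 and 1929 CPM and the protease inhibitor gene Serpinb2 at 194 and 643 CPM. With the same cluster weights the log2 ratio of Serpinb2 went from 1.68 to 0.40, and Krt15, Stfa1, Serpinb2, Sprr2d and BC100530 were no longer among the 12, while that of Defb6 went from 1.72 to 0.96 with the hair clusters left out. The 12 ranked lowest were Krt25, Tchh, Krt71, Krtap8-1, Krtap15, Krt27, Krt33a, Prr9, Krt28, S100a3, Krt73 and Fabp4, whose largest WT UMI sums by cluster all lay in the hair clusters, so they are not read as a difference within keratinocytes. Extracellular matrix genes had 22 of 24 members lower in these cells and a median of -0.60, which was -0.29 with the same cluster weights. The summed CPM of Col1a1, Col1a2 and Col3a1, the fibrillar collagen genes of fibroblasts, chosen after their values were seen, was 147 in WT and 19.8 in Card14KI keratinocytes.

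**Figure D3:**
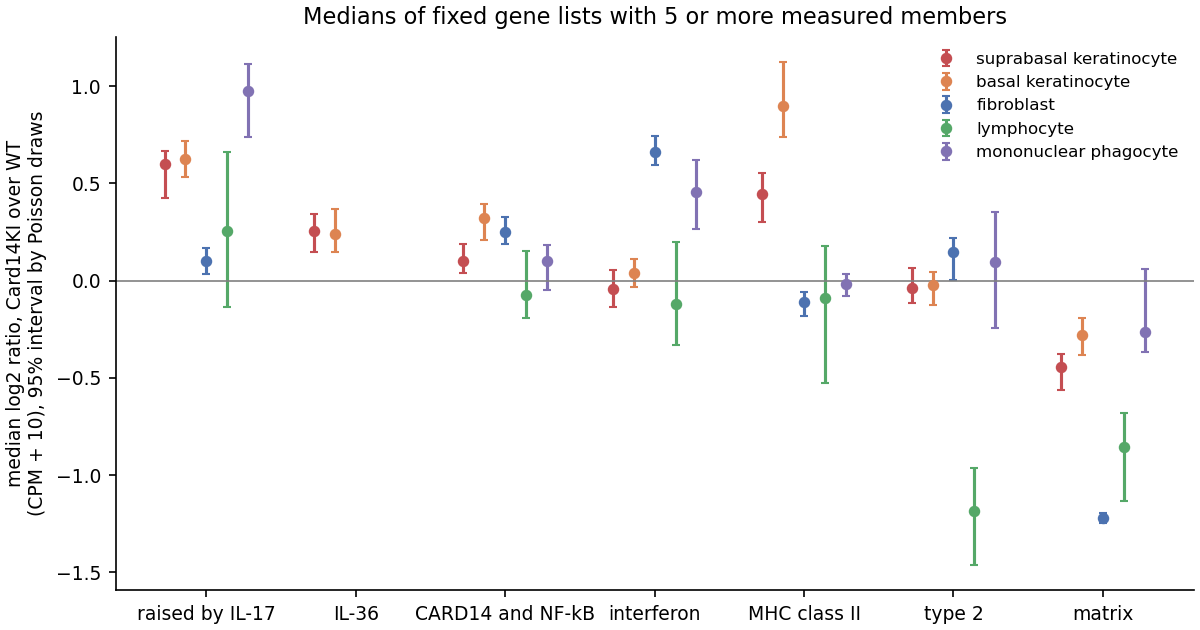
Median log2 ratio (Card14KI over WT, linear axis) of 7 gene lists in suprabasal and basal keratinocytes, fibroblasts, lymphocytes and mononuclear phagocytes, with intervals from Poisson draws as bars. Genes that IL-17 raises were at 0.60 in suprabasal and 0.62 in basal keratinocytes, and interferon response genes at 0.66 in fibroblasts.

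The next comparison asked which cells carried IL-17 and whether they differed. Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496, plus strand) was at 273 CPM (245 to 303) in WT lymphocytes and 524 CPM in Card14KI lymphocytes, a ratio of 1.92 (1.63 to 2.25). A UMI was found in 28 of 375 WT (7.47%, 5.02 to 10.6) and 19 of 147 Card14KI (12.9%, 7.96 to 19.4) lymphocytes. Thinned to 2000 UMIs the shares were 7.06% of 326 and 12.3% of 130 cells, leaving out 49 and 17, and the difference of 5.25 points (-0.40 to 12.4) lay within counting error. In fibroblasts 0.185% of WT cells and 0 of 1385 Card14KI cells had an Il17a UMI, and none after thinning. Lymphocytes had a median of 3171 and 3282 UMIs. The log2 ratio of 0.92 was 0.67 without the top cell of each library, 0.40 as a mean over cells and 1.34 with the stricter filter. No Il17a UMI lay in the 59 WT and 17 Card14KI cells of the gamma-delta T cluster, and those of lymphocytes all lay in the alpha-beta T cluster.

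The related cytokine genes gave no clear difference. Il17f was found in 24 WT (6.40%) and 7 Card14KI (4.76%) lymphocytes, and in 15 (4.60%) and 4 (3.08%) after thinning. Its level was 81.5 and 98.3 CPM, but 33 of 52 Card14KI UMIs lay in 1 cell and its log2 ratio turned from 0.24 to -0.70 without the top cells. Il22 (ENSMUSG00000074695, chromosome 10, 118204942 to 118210047, plus strand) was found in 0 of 375 WT lymphocytes, which allows up to 0.8% of cells with a UMI and sets no limit on cells expressing the gene, and in 2 of 147 Card14KI lymphocytes (1.36%), with 93 of its 94 UMIs in 1 cell. IL-17 and IL-23 ligands and receptors had 7 of 13 members higher and a median of 0.19 (-0.23 to 0.43), which turned to -0.094 as a mean over cells. Il23r, the IL-23 receptor gene, was at 13.8 and 51.1 CPM, a ratio of 3.69 (1.96 to 7.11), and Ccr6, the receptor of CCL20, was 2.93-fold lower (1.67 to 5.56). Il23a had a UMI in 7.67% of WT and 7.07% of Card14KI suprabasal keratinocytes, and in 1.31% of each after thinning. In fibroblasts Il23a was seen in 0.694% and 1.81% of cells.

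Type 2 cytokine genes were lower in Card14KI lymphocytes. Of 6 measured members 5 were lower, with a median of -1.19 (-1.46 to -0.96) at percentile 0, which was -0.20 with all members of 1 UMI or more. Il5, the eosinophil growth factor gene (ENSMUSG00000036117, chromosome 11, 53720794 to 53725106, plus strand), had 197 UMIs in WT and 0 in Card14KI, at least 26.7-fold lower. Il13 (ENSMUSG00000020383, chromosome 11, 53631324 to 53634702, minus strand), a driver of type 2 inflammation, was 7.24-fold lower (4.38 to 12.8), at 219 and 30.3 CPM. Gata3, the transcription factor gene of type 2 T cells, was 2.48-fold lower (1.99 to 3.13), and Il1rl1, which codes for the IL-33 receptor, 10.2-fold lower (5.73 to 19.9). In the alpha-beta T cluster Il5 was seen in 34 of 316 WT and 0 of 130 Card14KI cells, Il13 in 35 and 6, and Il1rl1 in 82 and 7. At resolution 2, 226 WT and 89 Card14KI cells were named alpha-beta T cell and 90 and 41 innate lymphoid cell, a type that also carries these genes. The member that went the other way, Il4ra, was at 92.2 and 123 CPM, a ratio of 1.33 (0.970 to 1.82).

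Of the genes ranked highest in Card14KI lymphocytes, Cd163l1, a scavenger receptor gene of gamma-delta T cells, was at 37.7 and 227 CPM (ratio 6.02, 4.29 to 8.58) and the activation gene Cd83 at 26.9 and 155 CPM (ratio 5.76, 3.84 to 8.82). Tmem158, Ckb, Gcnt2 and Avpi1 had ratios of 8.04, 4.86, 7.93 and 3.62. The lowest besides Il5, Il13 and Il1rl1 were the chemokine gene Ccl1, with 3 Card14KI UMIs (19.6-fold, 6.59 to 96.4), Nrgn (8.94-fold) and the vessel growth factor gene Vegfa (9.43-fold). T cell effector genes had 10 members higher and 13 lower, with a median of -0.01 (mean -0.24). Pdcd1, which codes for PD-1, and Ifng, the interferon gamma gene, had ratios of 1.92 (1.38 to 2.67) and 1.75 (1.29 to 2.37). Gzma was at 141 and 28.4 CPM, with all 15 Card14KI UMIs in 1 cell. Immediate early and heat shock genes had 17 of 20 members lower (median -0.28), cell cycle genes 16 of 20 (median -0.39) and MHC class I genes 10 of 12 (median -0.18). Chemokines had 6 members higher and 9 lower (median -0.51, mean -0.06), and the median turned to 0.47 over members with 50 UMIs or more. Of 7 measured IL-17-raised genes 4 were higher (median 0.26, but -0.04 over members with 50 UMIs or more), and of the members with the largest ratios Ccl20 had 44 of 45 and Cxcl3 21 of 26 Card14KI UMIs in 1 cell. Extracellular matrix genes were all lower (16 of 16, median -0.86, or -0.29 when doublets were kept), and the collagen sum in these cells was 267 and 32.1 CPM.

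In fibroblasts the question was whether the tissue around the epidermis differed. Interferon response genes were higher in Card14KI fibroblasts without exception, 22 of 22, with 12 of them at least 1.5-fold apart and a median of 0.66 (0.59 to 0.74) at percentile 100. Ifi27l2a (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680, minus strand) was at 438 and 2228 CPM, a ratio of 5.08 (4.95 to 5.22). Irf7, a transcription factor gene of the response, had a ratio of 3.52 (3.13 to 3.97), and the ubiquitin-like modifier gene Isg15 a ratio of 3.12 (2.87 to 3.39). The chemokine list had 10 members higher and 10 lower (median 0.01). Higher were Cxcl13, which draws B cells, at 153 and 542 CPM over the class, Ccl2, which draws monocytes, at 343 and 1181 CPM over the class, and Cxcl10, an interferon target, at 138 and 385 CPM, while Cxcl14 was 2.93-fold lower (2.71 to 3.16).

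Some members of the IL-17-raised, STAT3 and NF-kB lists were higher in Card14KI fibroblasts, while matrix genes were lower. Of the IL-17-raised list 4 members were at least 1.5-fold higher and 2 at least 1.5-fold lower, among them Saa3, a serum amyloid gene, at 89.5 and 24.1 CPM. The neutrophil chemokine genes Cxcl1 and Cxcl2 had ratios of 2.62 (2.55 to 2.69) and 2.60 (2.45 to 2.76). Il6 was at 139 and 396 CPM (ratio 2.85, 2.70 to 3.0), Socs3, its feedback gene, had a ratio of 1.83, and Rel and Nfkbiz of the NF-kB list had ratios of 1.91 and 1.79. The Wnt modulator gene Sfrp2 was at 98.4 and 288 CPM. Extracellular matrix genes had 21 of 24 members lower and a median of -1.22 (-1.25 to -1.19), and the collagen sum was 28047 CPM in WT and 9079 CPM in Card14KI, 3.09-fold lower over the class. The fold differed by cluster: Col1a1 was at 1819 and 1203 CPM in the cluster with most Card14KI cells and at 30855 and 9228 CPM in the one with the highest level. Mmp13, a collagenase gene, had 2228 WT UMIs, 683 of them in 1 cell, and 1 Card14KI UMI. Dcn, the decorin gene, went the other way, at 11400 and 13130 CPM. The genes ranked lowest, Spp1, Lrrc15, Acta2, Mmp11, Tagln and Col12a1, had more WT UMIs in a cluster with 306 WT and 40 Card14KI cells than in any other, and some of them define it. With the same cluster weights all 6 stayed lower, and their log2 ratios went from -3.55 to -2.62 for Spp1 and from -3.05 to -0.76 for Mmp11, the largest and the smallest that remained.

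Different clusters led the fibroblasts of each library: 1 with 446 WT and 219 Card14KI cells led in WT, and 1 with 373 and 510 cells led in Card14KI. With the same cluster weights in both libraries the interferon median was 0.35 in place of 0.66 and the matrix median -0.74. The log2 ratios of Ifi27l2a, Irf7 and Isg15 went from 2.32, 1.48 and 1.47 to 1.5, 0.91 and 0.98 with those weights, an alternative that was added for single genes after the data were seen, and those of Cxcl1 and Cxcl2 from 1.37 and 1.31 to 0.46 and 0.34, and of Rel and Nfkbiz from 0.81 each to 0.22 and 0.14. Those of Il6, Sfrp2, Ccl2 and Cxcl10 went from 1.44, 1.46, 1.75 and 1.41 to 0.73, 0.71, 0.99 and 0.93. Within clusters Ifi27l2a was at 1713 and 3825 CPM in the Card14KI-rich cluster and at 731 and 3352 CPM in the WT-rich one. In the Spp1 and Mmp11 cluster, with 86 and 2 UMIs, no difference could be told. MHC class I genes had 11 of 12 members higher (median 0.42), with H2-T23 at 105 and 182 CPM. Cxcl13 was at 506 and 1115 CPM in the Card14KI-rich cluster but lower in a cluster of 353 WT and 160 Card14KI cells, with 757 and 9 UMIs. In the same 2 clusters Ccl2 was at 1083 and 2193 CPM and at 293 and 292 CPM, and it was lower in the Spp1 and Mmp11 cluster, at 251 and 65.2 CPM with 8 Card14KI UMIs. CARD14 and NF-kB genes had a median of 0.25 (0.13 with the same weights), IL-36 genes 0.29, IL-17-raised genes 0.10, IL-17 ligands 0.06, type 2 genes 0.15 (-0.058 with the same weights), growth factor and STAT3 genes 0.01 (mean 0.18), T cell genes -0.04, hyperproliferative genes -0.08 and MHC class II genes -0.11. Immediate early and heat shock genes, which dissociation can raise, had 19 of 20 members higher (median 0.38, or 0.23 as a mean over cells), with Atf3 at 249 and 532 CPM. Whether dissociation had a part in the higher levels of Cxcl1, Cxcl2, Il6 and Socs3 was not tested. Cell cycle genes had 18 of 20 members lower (median -0.28).

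Mononuclear phagocytes of the Card14KI library carried more chemokine and interferon transcripts. Chemokines had 15 of 21 members higher and a median of 0.76 (0.67 to 0.92), which was 0.05 when doublets were kept, and interferon response genes 18 of 22 and 0.46 (0.27 to 0.62), which was 0.10 as a mean over cells. Immediate early and heat shock genes, which dissociation can raise, moved with them, with 16 of 20 members higher and a median of 0.24 (0.13 to 0.30) at percentile 99.87. The neutrophil chemokine genes Cxcl3 and Cxcl1 had ratios of 6.66 (4.40 to 10.4) and 2.93 (2.15 to 4.01), though 92 of the 93 Card14KI Cxcl3 UMIs lay in 6 cells, Isg15 4.34 (3.19 to 5.96) and Ifi27l2a 2.62 (2.44 to 2.83). Il10, the anti-inflammatory cytokine gene, was at 13.2 and 100 CPM (ratio 7.55, 4.53 to 13.1), and Hbegf, an EGF receptor ligand gene, at 14.6 and 88.3 CPM (ratio 6.06, 3.66 to 10.4). Both were also higher in the macrophage cluster alone, Il10 at 110 and 445 CPM and Hbegf at 110 and 367 CPM. The Il10 UMIs there, 16 in WT and 68 in Card14KI, lay in 6 and 7 cells, and in the cluster named monocyte Il10 had 4 and 0 UMIs. Macrophages were 34 of the 241 WT and 27 of the 111 Card14KI cells of this class, and 192 and 75 lay in a cluster named monocyte. That name is not settled: class II genes lead the cluster, and it was named conventional dendritic cell when clusters were named by the mean. No cluster was named monocyte when each library was clustered alone, where Langerhans cells were 204 and 84, and at resolution 2 monocytes were 46 and 21.

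Cxcl13 was 35.5-fold lower (20.2 to 69.0) in Card14KI phagocytes, and within the macrophage cluster, where it is among the defining genes, it was seen in 32 of 34 WT and 7 of 27 Card14KI cells. Mmp12, a macrophage elastase gene, was 5.02-fold lower (3.98 to 6.41). Spp1 had 111 UMIs in WT, 60 of them in 1 cell, and 0 in Card14KI, and Ttn had 54 and 0. Slc15a2 was 24.3-fold lower with 1 Card14KI UMI (4.18 to 978) and Ube2c, a cell division gene, 5.10-fold lower. Higher in Card14KI were also Lyz1, a lysozyme gene (ratio 5.34, 4.40 to 6.51), Plet1 with 3 WT UMIs (ratio 34.8, 11.2 to 175) and Retnla, a marker of type 2 activated macrophages (ratio 3.97, 3.77 to 4.18). Within the macrophage cluster, where Retnla is a defining gene, it was at 10466 and 19316 CPM, and in the monocyte cluster at 641 and 2570 CPM from 17 and 10 cells. Il1b was at 1041 and 1760 CPM, a ratio of 1.69 (1.57 to 1.82), and was seen in 46.5% and 45.9% of cells, or 38.4% and 41.0% after thinning, against 0.463% and 0.144% of fibroblasts, the background class, or 0.149% and 0.0782% after thinning. Thinned to 1000 UMIs the phagocyte difference was 10.9 points in place of 2.57. Cxcl2 was seen in 36.5% and 48.6%, or 35.6% and 47.0% after thinning, a difference of 11.3 points (-0.20 to 22.8) within counting error, which narrowly left it when thinned to 1000 UMIs (12.3 points, 1.69 to 23.1). Fibroblasts, which carry Cxcl2 themselves, had a UMI in 10.97% and 14.5% of cells, or 6.66% and 12.1% after thinning. The other IL-1 family list had a median of 0.50 and the IL-17-raised list 0.97 (0.20 with all members of 1 UMI or more), cell cycle genes had 18 of 20 members lower (median -0.34), MHC class II genes a median of -0.02, and T cell genes 0.71, which was 0.04 when doublets were kept. Il1b UMIs were seen in 44 of 45 WT and 33 of 33 Card14KI neutrophils, and Il1f9 UMIs in 46.7% and 57.6% of them.

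Sebocytes, the lipid-secreting gland cells, had 3 cytochrome P450 genes among the 6 ranked lowest in Card14KI. Cyp2g1 was 107-fold lower (81.4 to 143) in Card14KI, at 1206 and 11.3 CPM, Cyp2f2 was 24.3-fold lower, and Cyp17a1, a steroid hydroxylase gene, 20.2-fold lower (14.9 to 28.2). Agpat2, a lipid synthesis enzyme gene, was 4.22-fold lower (3.73 to 4.79), Klhl2 3.88-fold and Armcx1 3.50-fold. Higher in Card14KI were Hamp2, a hepcidin gene, at 9.14 and 97.51 CPM (ratio 10.7, 7.80 to 14.95), Pdzk1ip1 (4.45), Abcc3, a transporter gene (3.70), Plet1 (3.61), Rnase2b (4.18) and Arc (5.25). Cell cycle genes had 19 of 20 members higher and a median of 0.61 (0.50 to 0.71), which was 0.38 as a mean over cells, with the mitosis genes Cenpf at 3.40 and 25.2 CPM and Birc5 at 2.13 and 19.4 CPM. IL-17-raised genes had 6 of 7 members higher (median 0.56, but 0.030 with all members of 1 UMI or more), with Zc3h12a at 15.5 and 35.6 CPM. MHC class I genes had 11 of 12 members lower (median -0.25). MHC class II genes had 6 of 6 lower, but 186 of the 203 WT Cd74 UMIs lay in 1 cell, and its log2 ratio went from -2.06 to -0.19 without the top cells.

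Lymphatic endothelial cells, 102 in WT and 76 in Card14KI, were below the size set for ranking genes, so only lists were compared. Immediate early and heat shock genes, which dissociation can raise, had 20 of 20 members higher in Card14KI and a median of 1.14 (1.10 to 1.21). The stress gene Atf3 was at 389 and 1857 CPM and the heat shock gene Hspb1 at 504 and 1622 CPM. IL-17-raised genes had 6 of 6 higher and a median of 0.97 (0.80 to 1.29). Csf3, which codes for the neutrophil growth factor G-CSF, had 0 UMIs in WT and 184 in Card14KI, at least 65.0-fold higher, with 69 of them in 1 cell, and Cxcl2 had a ratio of 7.89 (5.72 to 11.1), with 115 of 320 UMIs in 1 cell. Chemokines had 6 of 8 members higher (median 0.60), which turned to -0.032 with all members of 1 UMI or more. Neutrophils had 11 of 13 NF-kB list members lower (median -0.79). Sex-linked genes had a median of -0.11 in keratinocytes, but the list mixes X genes such as Xist with Y genes such as Ddx3y. This median therefore cannot show whether both mice were of one sex.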

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

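The test of the suprabasal cluster mix and the test of free RNA in other classes were chosen only after the results they bear on were seen.

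Several gene lists went opposite ways in classes of the same libraries, and none of these differences was tested. MHC class I genes had a median log2 ratio of 0.53 in keratinocytes and -0.25 in sebocytes, but 0.069 in keratinocytes with the same cluster weights in both libraries. MHC class II genes had 0.74 in keratinocytes and -1.25 in sebocytes (-0.32 with all members of 1 UMI or more), where 1 WT cell held most UMIs of the leading members. Cell cycle genes had 0.61 in sebocytes and -0.39 in lymphocytes. Immediate early and heat shock genes had 0.48 in keratinocytes and -0.28 in lymphocytes, but 0.039 in keratinocytes with the same cluster weights. Type 2 inflammation genes had 0.15 in fibroblasts, with a lower counting bound of 0.003 and -0.058 under the same cluster weights, and -1.19 in lymphocytes (-0.20 with all members of 1 UMI or more). Among barcodes outside the comparisons, those with over 50% haemoglobin UMIs were 5.14% (4.41 to 5.94) of the Card14KI and 2.31% (1.91 to 2.77) of the WT barcodes, and 1 of them, in WT, was among the kept cells.

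S100a8 and S100a9 were higher in Card14KI suprabasal keratinocytes, and both are also the leading transcripts of neutrophils. Neutrophil RNA, free or in doublets, would bring the other neutrophil transcripts along, but these were at 4.66 CPM in WT and 7.18 CPM in Card14KI suprabasal cells, 6.07% (0.821 to 11.3) of the excess of 41.6 CPM that the S100a9 excess would need. A different mix of suprabasal clusters would leave at least 1 cluster with little difference, but the lowest log2 ratio of S100a9 among the 3 clusters was 2.20. Both explanations are excluded as the whole cause. A difference between these animals, the genotype included, stays open as a hypothesis that 1 mouse per group cannot test.

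Interferon response genes were higher in Card14KI fibroblasts with a median of 0.66. A different mix of fibroblast clusters can account for part of this, since with the same cluster weights in both libraries the median was 0.35 (0.34 to 0.47). That was narrowly above the bound of 0.33 set in advance for excluding the mix as the whole cause. However, the interval was drawn from UMI sums of the whole class and leaves out the added counting error of small clusters. The margin over 0.33 is therefore too narrow to call. A mix of these clusters as the whole cause would leave no rise with the same weights, so the median of 0.35 argues against that for the list. A finer mix of cells within clusters was not tested. Free RNA shared by every class was expected to raise the list as much in lymphocytes and keratinocytes as in fibroblasts. It stood at -0.12 in lymphocytes, and the higher of the upper counting bounds in those 2 classes was 0.20, which excludes an equal rise. Free RNA need not shift classes alike, however: the collagen sum was 8.30-fold lower in Card14KI lymphocytes and 1.61-fold lower in mononuclear phagocytes. The interferon list was also at 0.46 in mononuclear phagocytes, so an unequal share of free RNA stays open. An infection or another local event in 1 animal may give the same pattern as the genotype, and neither was tested.

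The clusters named hair follicle and hair shaft or matrix, the latter led by inner root sheath genes, lay almost wholly in the WT library, with 393 cells against 10, although a Krt17 and Krt79 cluster found in both libraries brought hair follicle cells to 401 and 209 when clusters were named by the mean of the others. Had Card14KI cells of those clusters been lost in cell calling or filtering, their free RNA would remain, but the hair transcripts in Card14KI fibroblasts, at 4.46 CPM, were 3.08% (2.14 to 4.11) of the 144 CPM in WT fibroblasts, which excludes that loss as the whole cause. A different stage of the hair cycle in the 2 mice stays open: pigment genes of the melanocyte cluster, which rise in hair growth, were 1.26-fold higher (1.11 to 1.44) in WT, between the bounds set for either outcome. That cluster also held Schwann cell genes, and no cluster was named melanocyte with either other cell filter, with response genes kept in, or in WT when each library was clustered alone, so the test is weak. The hair cycle and the genotype cannot be told apart here, and loss of hair follicles before cells entered droplets was not tested.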

How the results depend on the processing

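The alternatives that left out the hair clusters, named clusters by the mean of the others, used the same cluster weights for single genes outside keratinocytes, or left out each gene's top cells were chosen only after the results were seen.

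No paired analysis was possible because each group holds 1 mouse. Class shares kept their direction and stayed within their intervals in 72 of 77 values over 9 results, moved beyond them in 4 and reversed in 1. Shares of cells with a cytokine UMI stayed within them in 136 of 144, list medians in 927 of 1263, with 307 moved and 29 reversed, and named genes in 1286 of 2118, with 807 moved and 25 reversed. Depth limits rare cytokines and classes under 100 cells. For every value below the cause was not tested, except that cluster weights and left-out hair clusters remove differences in cluster mix by construction. Values are log2 ratios or list medians unless given in points.

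With no cell filter the keratinocyte share difference was 2.80 points. Here and with the stricter filter no cluster was named hair follicle keratinocyte, so the basal and suprabasal classes held other sets of cells. Basal keratinocyte genes were then Ccl20 -0.25, Nppb -0.28, Epgn -0.44, Emb 0.13, Cxcl2 -0.46, Lcn2 1.09, Tnfaip3 -0.35, Cd74 -0.46 and Il1f5 -0.44. Basal lists were IL-36 -0.44, other IL-1 family -0.32, CARD14 and NF-kB -0.053, hyperproliferative -2.42, cornified envelope -0.13, hemidesmosome -0.21, cell cycle 0.12, MHC class II -0.18, MHC class I -0.49 and growth factor -0.18. In suprabasal cells Ccl20 was 0.033 and immediate early genes 0.17.

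With the stricter filter the keratinocyte share difference was 9.04 points, the keratinocyte IL-17-raised list 0.87, sebocyte hemidesmosome genes -0.043, suprabasal Ccl20 0.12 and suprabasal immediate early genes 0.048. With no doublets removed suprabasal cell cycle genes were -0.020 and immediate early genes 0.030. With each library clustered alone the B or plasma cell difference was -1.18 points and the sebocyte difference 3.25 points. With clusters named by the mean of the others the fibroblast difference was 5.30 points.

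With the same cluster weights fibroblast type 2 genes were -0.058. In keratinocytes Il17b was 0.059, Card14 0.056, Malt1 -0.12, Traf2 -0.11, Nfkb1 -0.18, Nfkb2 -0.037, Nfkbia -0.0033, Cyld -0.073, the IL-17-raised list 0.51 and the CARD14 list 0.10. In basal cells Lcn2 was 0.38, hemidesmosome genes -0.054, cell cycle genes 0.039, MHC class I -0.13 and growth factor genes -0.018. With hair clusters left out, keratinocyte Il17b was 0.0034, Lcn2 -0.46, Card14 -0.10, Malt1 -0.10, Traf2 -0.048, Cyld -0.11, and the lists IL-17-raised 0.43, IL-36 0.14, CARD14 0.23, hyperproliferative 0.11 and interferon response -0.014.

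As a mean of each cell's CPM, fibroblast type 2 genes were -0.018, keratinocyte Card14 0.68, the CARD14 list 0.35, hyperproliferative genes 0.38, keratinocyte cell cycle genes -0.057, sebocyte hemidesmosome genes -0.023 and basal cell cycle genes 0.15. With members of 1 UMI or more, endothelial chemokines were -0.032, fibroblast type 2 genes -0.0076, keratinocyte IL-17-raised genes 0.11 and basal hyperproliferative genes -0.013. With members of 50 UMIs or more, fibroblast T cell genes were 0.091, keratinocyte IL-17-raised genes 0.93 and hyperproliferative genes 0.48.

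In keratinocytes, median-of-ratios scaling gave 0.87 for the IL-17-raised list and 0.49 for the CARD14 list. A pseudocount of 1 CPM gave Card14 0.53, IL-17-raised 1.08, IL-36 0.76, CARD14 0.54 and hyperproliferative 0.51. Without mitochondrial, ribosomal and haemoglobin genes the IL-17-raised list was 0.86 and the hyperproliferative list 0.26.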

Other observations

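No test of this part was chosen after its result was seen, although the marker genes of the gamma-delta test include Cd163l1 and Trdv4, which had been seen among the genes ranked in alpha-beta T cells before the test was written. The same cluster weights for single fibroblast genes, the values per cluster and the collagen sum were chosen after the data were seen.

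The chemokine Cxcl13 differed in direction between the cell groups that carry it. In the macrophage cluster it was at 6513 CPM in WT and 78.5 CPM in Card14KI, with 944 and 12 UMIs. Over all fibroblasts it was at 153 and 542 CPM, but with the same cluster weights the log2 ratio was 0.75 in place of 1.76, and fibroblast clusters went both ways. It was higher in Card14KI in clusters of 373 WT and 510 Card14KI cells (506 and 1115 CPM) and of 139 and 106 cells (561 and 961 CPM), and lower in clusters of 353 and 160 cells (757 and 9 UMIs) and of 446 and 219 cells (27.1 and 8.22 CPM). No difference between these groups was tested. Fibrillar collagen transcripts were lower in the Card14KI library beyond fibroblasts as well, with the sum of Col1a1, Col1a2 and Col3a1 at 102 and 9.82 CPM in sebocytes and at 259 and 39.0 CPM in lymphatic endothelial cells, which do not make them in bulk. In mononuclear phagocytes, where they were least apart, the sum was 488 and 303 CPM.

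Il17a UMIs lay in the cluster named alpha-beta T cell in both libraries, and none lay in the gamma-delta T cluster. As a hypothesis, the Il17a-positive cells could be gamma-delta T cells placed among alpha-beta cells, and 21 of 47 of them (44.7%, 30.2 to 59.9) had a UMI of Trdc, Trdv4 or Cd163l1, against 58 of 399 (14.5%) of the Il17a-negative cells of that cluster and 76 of 76 (95.3 to 100) of the gamma-delta T cluster, a share that is no independent reference because Trdc helps to define that cluster. The interval spans the 50% set in advance for either outcome, so the test leaves open what share of them are gamma-delta cells. A UMI of Trac, Trbc1 or Trbc2 was found in 42 of the 47 (89.4%), but also in 84.2% of the gamma-delta T cluster, so it does not part the types. By library the share with a gamma-delta UMI was 12 of 28 in WT and 9 of 19 in Card14KI.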
